A study of Mus musculus with 11 samples.

How the data were processed

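Total RNA from mouse esophageal tissue labelled as epithelium was sequenced on Illumina libraries, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.12, STAR 2.6.90c and featureCounts 1.5.1 with the mouse build mm10. The notes give no role, order or setting for these tools, and the strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. The authors deposited 1 table of raw read counts per gene for the whole series, with 54532 genes, their symbols and coordinates. The gene length in the same table is the authors' deposited value in bases, and its unit was entered as other. Counts were whole numbers that summed to a different total in each library, and no normalization was applied to them by the authors as far as the values show.

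The 11 library columns are named with a letter and a number that appear in no label. A column was given to a group only where the lettered sets and the label groups left 1 choice. Sets A and B have 4 columns each and set C has 3. The groups have 4, 4 and 3 samples. Set C (C1, C3 and C4) was therefore taken as mutant PYR, under the assumption that a letter marks a group. Column order and values were not used for this. The replicate number of each C column is unknown. The 8 columns of sets A and B were not used in any step, since assigning them to control vehicle or mutant vehicle would have needed column order or the values. The planned comparisons (mutant vehicle against control vehicle, mutant PYR against mutant vehicle, mutant PYR against control vehicle, the tests of gene lists, and the count of genes changed back by PYR) were not run. No p-value between groups is reported.

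The steps below were chosen after the columns had been inspected. Gene counts of the 3 libraries were passed to edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 13784, and library sizes were scaled by TMM (trimmed mean of M-values), with factors of 1.00 for C1, 1.04 for C3 and 0.961 for C4. The common biological coefficient of variation was estimated with an intercept-only model. CPM was computed from the deposited counts and the TMM-scaled totals, and each value is given as mean ± SD over 3 libraries or per library. The spread of a gene was the SD of log2(CPM + 0.5) between libraries. Level percentiles rank genes past the filter by CPM per kilobase, using the deposited gene length. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

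A total of 35 gene lists with 730 genes was fixed before the data were examined. They cover NRF2 targets and regulators, other antioxidant enzymes, glycolysis, oxidative phosphorylation, folate metabolism, the ATF4 and unfolded protein responses, p53 targets, replication, mitosis, keratinocyte states, signalling targets, interferon, inflammation, lipid synthesis, xenobiotic response, proteasome, ribosome, immediate early and heat shock genes, other cell types and sex-linked genes. A list's value in a library is the median CPM of its members past the filter. Its spread is the median of its members' SDs, placed among 10000 random lists of the same size matched on mean expression in 50 bins. This percentile describes these libraries and is not a test of a group. In all, 3 genes stand in more than 1 list. Of the list symbols, 4 were not in the table, and each is a newer alias of a gene listed under its older symbol. Where a symbol had several IDs (103 rows), the ID with the most reads was used.

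The naming rule fixed before the data were examined asked for 16 genes in every comparison, of which 1 is not reported here. The others are Nfe2l2, Keap1, Sox2, Nqo1, Gclc, Gclm, Hmox1, Txnrd1, Tyms, Mki67, Krt5, Krt14, Krt4, Krt13 and Cdkn1a. Its other parts needed a comparison. In their place the 10 most abundant genes, the 10 protein-coding genes past the filter with the largest spread at a mean of 2 CPM or more, and members of lists were named, all chosen after their values were seen. Symbols of clones, gene models and pseudogenes were left out of those 10. Genes that did not pass the filter, such as Cfd with an SD of 3.49, were outside this choice.

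Of the table's gene IDs, 54409 were in GENCODE mouse release 21, and 53499 of those (98.3%) had the same coordinates there, while 123 IDs were not in it. Coordinates are those of the table. Totals of assigned reads were 24181764 in C1, 19730722 in C3 and 18138820 in C4. Genes with a read numbered 20804, 21033 and 19617. A total of 13959 genes had 10 reads or more in all 3 libraries at once, and 30561 genes had no read in any of the 3. Mitochondrial genes took 2.16%, 2.22% and 2.94% of reads, and protein-coding genes 98.0%, 97.9% and 98.2%. The floor given for a library is 3 counts over its total.

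The steps were tested on simulated data made from the means and sizes of the 3 mutant PYR libraries over 13784 genes. A coefficient of variation of 20% was recovered as 19.95%. Of 200 genes given extra spread (SD 2 on the log2 scale), 86% were among the 200 with the largest SD. Of 40 lists of 20 genes in which a portion had extra spread, 40 lay above the 95th percentile, as did 0 of 40 lists without any. The simulated genes varied independently of each other. They were therefore no check of the percentile for lists whose members vary together.

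Alternatives were other scaling factors (RLE, upper-quartile or none beyond the total), no filter on low counts, a filter of 1 CPM in 3 libraries, counts thinned to the smallest total and leaving out each library, both with the filter run again and with the 13784 genes kept. Shared reads were checked on GENCODE transcripts and exons with stretches of 50 bases. No genome sequence was used here.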

Results

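Bulk RNA sequencing was carried out on esophageal epithelium from mice of 3 labelled groups, harvested at week 3. Control mice carried only Sox2CreER, a tamoxifen-inducible Cre recombinase driven from Sox2, and received vehicle. The mutant mice also carried an allele that Cre switches on and that encodes NRF2 with the E79Q change. NRF2, the product of Nfe2l2, is the transcription factor that switches on antioxidant and detoxification genes and is held in check by KEAP1. Mutant mice received either vehicle or pyrimethamine (PYR), an antifolate drug used against parasites that the series title names as an NRF2 inhibitor. The labels list 4 control vehicle, 4 mutant vehicle and 3 mutant PYR samples.

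The deposited count table names its 11 library columns with a letter and a number that match no label. The letters form sets of 4, 4 and 3 columns. The set of 3, columns C1, C3 and C4, was taken as the mutant PYR group because only that group has 3 samples. This rests on the assumption that a letter marks a group, which no label states. The other 8 columns could not be assigned to either vehicle group and were not used. No comparison between genotypes or between PYR and vehicle was therefore made, and the values below describe levels and the spread between libraries within the mutant PYR group. The labels number the samples but do not say that each came from a separate mouse, so the SD may be partly technical. Library C1 held 24181764 reads assigned to genes, C3 held 19730722 and C4 held 18138820. Levels are given as CPM, counts scaled to a common library total. A count of 0 allowed up to 0.124, 0.152 and 0.165 CPM in C1, C3 and C4, which covers counting error only.

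The typical NRF2 target gene lay among the most abundant transcripts of the mutant PYR libraries. The glutathione and thioredoxin targets had a median of 713 ± 31.1 CPM (SD, n = 3), and all 19 of 19 members passed the filter on low counts. Their typical member lay at the 97.6th percentile of expressed genes by reads per kilobase. The list was led by Slc7a11, the cystine importer, at 2907 ± 463 CPM, Prdx1, a peroxiredoxin, at 2787 ± 523 CPM, and Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, at 2485 ± 314 CPM. Srxn1, which repairs oxidized peroxiredoxins, had 1892 ± 278 CPM. Gclm, the partner subunit of Gclc, had 1033 ± 115 CPM, and Txnrd1, thioredoxin reductase, had 363 ± 61.4 CPM (n = 3 for each).

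The detoxification and iron targets had a median of 315 ± 19.7 CPM (SD, n = 3), with 43 of 44 members past the filter and a typical member at the 96.1st percentile. Gstm1, a glutathione S-transferase, was the fourth most abundant gene of all, at 10188 ± 1464 CPM. Aldh3a1, an aldehyde dehydrogenase, followed at 5643 ± 794 CPM, Ptgr1, which reduces reactive alkenals, at 4829 ± 533 CPM, and Adh7, an alcohol dehydrogenase, at 4045 ± 240.5 CPM. Nqo1, the quinone reductase often read as an NRF2 target, had 1137 ± 131 CPM. Hmox1, heme oxygenase, was lower and more variable at 285 ± 98.2 CPM, with 271 CPM in C1, 389 CPM in C3 and 194 CPM in C4. Together the detoxification list held 3.97% ± 0.349 of all counts and the glutathione list 1.97% ± 0.132. Reads of the Gstm and Gsta families may be split between close paralogs, so single members are uncertain.

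The spread of the glutathione list between libraries lay at the 48.7th percentile of random lists matched on expression, and that of the detoxification list at the 94.2nd. Library C1 had the highest value for 9 of the 19 glutathione members and C4 for 8, while 10 were lowest in C3. Of the 43 detoxification members, 19 were highest in C1 and 22 lowest in C4. With C1 left out, the detoxification median was 303 CPM over the same members, and 278 CPM where the filter was also run again and the members changed.

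**Figure D1:**
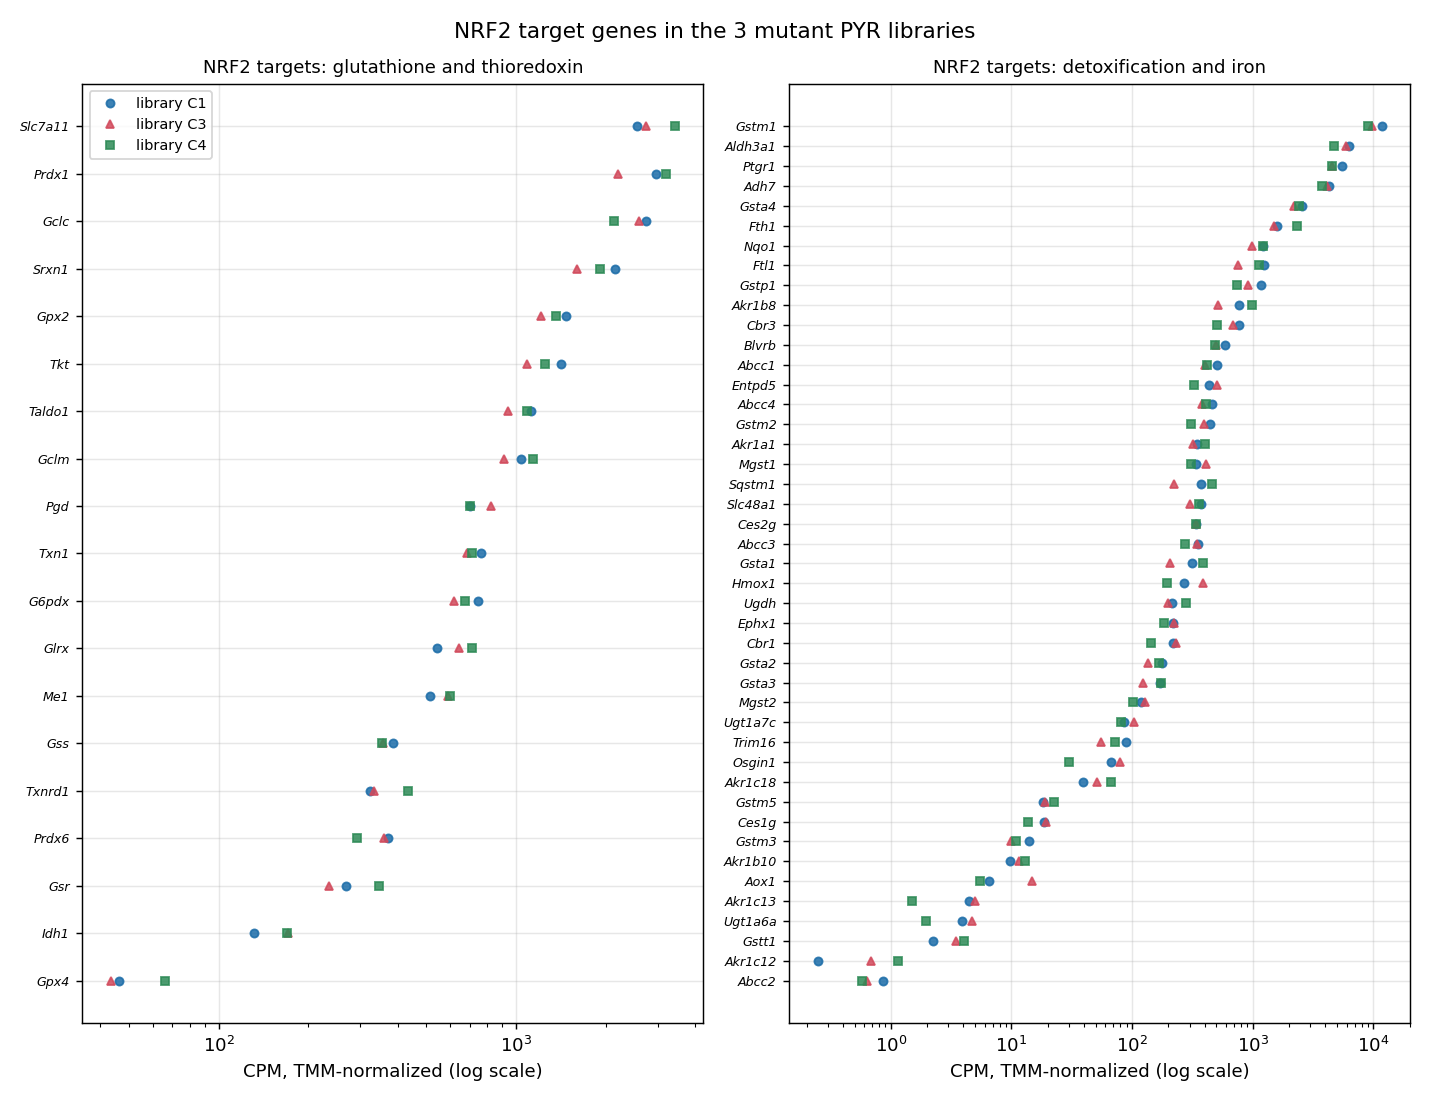
TMM-normalized CPM (log scale, horizontal axis) of each NRF2 target gene with reads in all 3 mutant PYR libraries, with 1 point per library (C1, C3 and C4) and genes ordered by their mean. Slc7a11 tops the glutathione and thioredoxin list with a mean of 2907 CPM and Gstm1 the other with 10188 CPM, while Hmox1 ranges from 194 CPM in C4 to 389 CPM in C3.

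The list of 11 NRF2 pathway regulators had a median of 81.5 ± 4.02 CPM (SD, n = 3), below those of both target lists, with a spread at the 16.6th percentile. Nfe2l2 (chromosome 2, 75675513 to 75704641, minus strand, mm10) had 301 ± 50.5 CPM, with 334, 325 and 242 CPM in C1, C3 and C4. Its counts do not tell the mutant allele from the normal one. Keap1, the adaptor that marks NRF2 for breakdown, had 74.1 ± 7.44 CPM. Antioxidant enzymes outside the NRF2 lists had a median of 97.2 ± 43.9 CPM, and 11 of 17 were highest in C4. Among them, Cat, catalase, had 593 ± 45.9 CPM and Gpx1 had 457 ± 184 CPM.

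Keratins and cornified envelope genes took a large part of the counts. Krt13 (chromosome 11, 100117327 to 100121566, minus strand), the suprabasal keratin of esophagus, was the most abundant gene at 18871 ± 3453 CPM (SD, n = 3). Krt6b followed at 10421 ± 3147 CPM, after the mitochondrial gene mt-Co1 at 11284 ± 2435 CPM, and Gsto1, an omega-class glutathione transferase, had 9783 ± 1593 CPM. Lor, encoding loricrin, had 6395 ± 2075 CPM and Slpi, a secreted protease inhibitor, 6664 ± 205 CPM. The translation factor gene Eef1a1 had 7883 ± 257 CPM. The suprabasal and cornified list held 6.45% ± 0.857 of all counts, with 51 of 54 members past the filter and a median of 339 ± 46.6 CPM. Of those 51 members, 23 were highest in C3 and 24 in C4.

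Keratinocyte genes differed widely between the 3 libraries. Krt4 (chromosome 15, 101918535 to 101924735, minus strand), which normally pairs with Krt13, had 812 CPM in C1, 5089 in C3 and 323 in C4, a mean of 2075 ± 2622 CPM (SD, n = 3) that was 558 CPM without C3. Krt1, a keratin of cornifying epithelium, had 1072 CPM in C1, 5632 in C3 and 260 in C4, and Krt10, its partner, had 1206, 2755 and 715 CPM in the same order. In contrast, Sprr2d, a cornified envelope precursor, had 348 CPM in C1, 260 in C3 and 2396 in C4, and Sprr2f had 123, 28.7 and 769 CPM. The Sprr2 genes are near-identical copies, and their single values are uncertain. The spread of the suprabasal list exceeded that of all 10000 random lists matched on expression, and so did the spread of the basal list and of the stress and wound list.

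Among basal genes, Krt5 had 3498 ± 576 CPM and Krt14 5987 ± 3043 CPM (SD, n = 3), the latter with 6399 CPM in C1, 2759 in C3 and 8802 in C4. Sox2, the transcription factor gene that the Cre line is named for, had 42.8 ± 17.7 CPM, with 23.2 CPM in C4. Trp63, the master regulator of stratified epithelium, had 307 ± 58.4 CPM. The basal list had a median of 110 ± 28.4 CPM, and 11 of its 19 members past the filter were lowest in C3. The stress and wound list had a median of 87.1 ± 23.5 CPM, with 23 of 28 members past the filter, of which 17 were highest in C4 and 14 lowest in C3. Without a filter on low counts that median was 45.5 CPM. Krt16, a keratin of wounded and hyperproliferative epithelium, had 6078 CPM in C1, 2000 in C3 and 9604 in C4, and Krt17 had 564, 133 and 1212 CPM. These keratin genes have close paralogs or pseudogenes with which reads may be shared. S100a8, a calprotectin subunit gene, had 65.6 CPM in C1, 39.6 in C3 and 1129 in C4, and its partner S100a9 had 104, 162 and 823 CPM.

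Several epithelial genes were among the 10 protein-coding genes past the filter that had the largest spread between libraries at a mean of 2 CPM or more. Serpinb3c (chromosome 1, 107271201 to 107278371, minus strand), a serine protease inhibitor gene with close paralogs, had 14.5 CPM in C1, 648 in C3 and 0.860 in C4. Flg, encoding filaggrin, had 13.0, 336 and 3.84 CPM in the same order, and Krt15, a basal keratin, 19.9, 66.6 and 2.24 CPM. Dapl1 had 41.8 CPM and Fa2h, a fatty acid hydroxylase, 35.5 CPM in C3, against 2.39 and 1.36 CPM in C1 and 0.574 and 2.06 CPM in C4. Slc6a14, an amino acid transporter, went the other way, with 10.8 CPM in C1, 4.21 in C3 and 265 in C4. Plet1 had 46.0, 3.81 and 205 CPM, and Sfrp4, a secreted Wnt modulator, 6.18, 1.22 and 66.2 CPM. S100a8 and Sprr2f complete the set. These libraries belong to 1 group, and single genes were not tested between them.

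Folate pathway genes were set out as a list because pyrimethamine is an antifolate. Tyms, thymidylate synthase, had 13.5 ± 0.918 CPM (SD, n = 3). The folate and one-carbon list had a median of 30.7 ± 5.32 CPM, with 27 of 30 members past the filter. Mat2a, which makes S-adenosylmethionine, led it at 163 ± 45.7 CPM, followed by Ggh, which trims folate polyglutamates, at 125 ± 31.2 CPM. Folr1, a folate receptor gene, had 0 reads in all 3 libraries. The spread of the list lay at the 94.8th percentile of matched random lists.

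Transcripts of cycling cells were detected in every library. The DNA replication list had a median of 15.5 ± 1.29 CPM (SD, n = 3), with a spread at the 10.2nd percentile, and Pcna, the replication clamp, had 86.8 ± 3.67 CPM. The mitosis list had a median of 18.8 ± 2.19 CPM, and 20 of its 28 members were lowest in C3. Mki67, a marker of cycling cells, had 78.3 ± 13.4 CPM and Top2a 90.5 ± 8.45 CPM. The p53 target list had a median of 38.9 ± 2.02 CPM, with a spread at the 76.6th percentile. Cdkn1a, the cell cycle inhibitor p21, had 313 ± 11.1 CPM, and Perp, a desmosome gene under p53 and p63 control, 3653 ± 316 CPM.

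Transcripts of cells other than keratinocytes were present in every library, although the label names epithelium. The fibroblast list had medians of 70.0 CPM in C1, 49.7 in C3 and 142 in C4, and 15 of 15 members were highest in C4 and lowest in C3. Col3a1, a fibrillar collagen gene, had 329, 119 and 2688 CPM in C1, C3 and C4. Leukocyte genes went the same way, with medians of 29.4, 18.3 and 58.1 CPM and all 16 of the 26 members that passed the filter highest in C4. Without a filter on low counts the mean of the leukocyte medians was 5.25 CPM. Lyz2, a lysozyme of macrophages and neutrophils, had 167, 81.9 and 438 CPM. Smooth muscle genes had medians of 42.5 CPM in C1, 104 in C3 and 50.6 in C4, with 10 of 10 members highest in C3. Skeletal muscle genes, typical of the striated muscle coat of mouse esophagus, had medians of 20.6, 87.3 and 80.5 CPM, with 15 of 17 members past the filter, of which 14 were lowest in C1. Acta1, skeletal actin, had 194 CPM in C1, 803 in C3 and 891 in C4. Endothelial genes had a median of 38.8 ± 5.82 CPM (SD, n = 3) and a spread at the 76.6th percentile. C4, the library with the highest fibroblast and leukocyte medians, also had the highest median of the stress and wound list. Of that list, Krt16 and Krt17, keratins of epithelium, were themselves highest in C4. For other members, S100a8 and S100a9 among them, bulk counts do not tell whether keratinocytes or leukocytes made the transcripts.

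**Figure D2:**
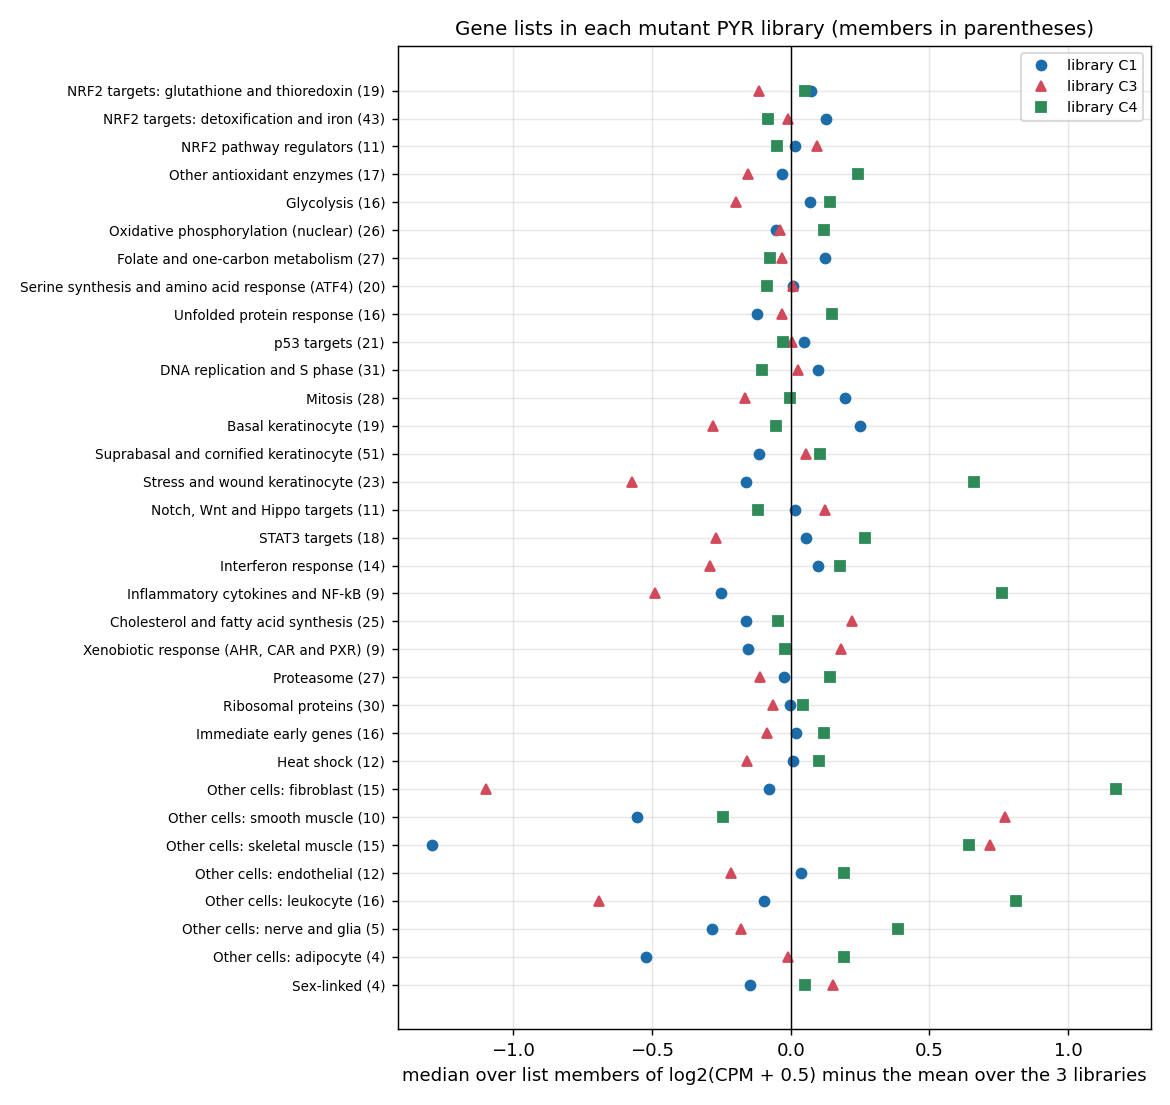
For each gene list (vertical axis, number of members past the filter in parentheses), the median over members of log2(CPM + 0.5) in each mutant PYR library minus the mean over the 3 libraries (horizontal axis), with 1 point per library. The fibroblast list runs from -1.10 in C3 to 1.17 in C4 and the stress and wound list from -0.57 to 0.66, while the glutathione and thioredoxin list of NRF2 targets stays between -0.11 and 0.07.

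Inflammatory and STAT3-linked genes also varied between libraries. The inflammatory list had a median of 34.1 ± 13.3 CPM (SD, n = 3) over the 9 of 25 members that passed the filter, and 8 of the 9 were highest in C4. Without C3 the median was 40.6 CPM over the same members, and 12.6 CPM where the filter was also run again. Without a filter on low counts it was 3.28 CPM. Nfkbia, an inhibitor of NF-kB that is itself induced by it, had 231 CPM in C1, 185 in C3 and 405 in C4. The STAT3 target list had a median of 59.0 ± 14.6 CPM, with 12 of 18 members highest in C4 and 12 lowest in C3. The interferon list was low, at 4.91 ± 1.60 CPM over 14 of 29 members, and at 1.03 CPM without the filter. Cholesterol and fatty acid synthesis genes had a median of 202 ± 20.8 CPM, and 23 of 25 were highest in C3. Hmgcs1, an early enzyme of the mevalonate pathway, had 229, 413 and 281 CPM in C1, C3 and C4.

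Among genes of central cell functions, ribosomal protein genes had a median of 875 ± 22.2 CPM (SD, n = 3), and none of the 10000 matched random lists had a smaller spread. The proteasome list had 151 ± 13.7 CPM and the oxidative phosphorylation list 105 ± 7.79 CPM, with spreads at the 6.01st and 5.18th percentiles. Still, 20 of 27 proteasome and 21 of 26 oxidative phosphorylation members were highest in C4, so these low spreads held small shifts in a shared direction. The glycolysis list had 267 ± 23.9 CPM, the heat shock list 122 ± 8.86 CPM and the unfolded protein response list 115 ± 4.53 CPM. The serine synthesis and ATF4 list had 99.2 ± 7.47 CPM, led by Slc3a2, the partner chain of several amino acid transporters, at 802 ± 94.5 CPM. Immediate early genes had 57.6 ± 5.55 CPM. The Notch, Wnt and Hippo list had 16.9 ± 4.11 CPM over 11 of 17 members. The xenobiotic response list had 18.2 ± 3.95 CPM over 9 of 13 members, with a spread above that of all 10000 matched random lists. Without a filter on low counts these medians were 5.42 and 5.48 CPM, and with 1 CPM required in 3 libraries they were 29.7 and 34.2 CPM.

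The common biological coefficient of variation over 13784 genes was 28.3%, and over the same genes it ranged from 23.3% without C4 to 33.0% without C1. No pair of libraries agreed within counting error, the only error that the measure covers, with a chi-square per degree of freedom from 54.7 to 103. This does not tell separate mice from repeated preparations of the same tissue. A total of 33 lists had enough members for a spread. Of these, 13 lay above the 95th percentile of matched random lists and 1 lay below the 5th.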

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

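All alternatives here were chosen after seeing the data, because the planned ones belong to comparisons between groups that were not run. No paired analysis was possible because the columns carry no replicate number of the labels and only 1 group could be identified. Without a filter on low counts the number of genes rose from 13784 to 23971 by construction, the coefficient of variation was 37.8%, the median of the NRF2 detoxification and iron list was 294 CPM and that of the stress and wound list 45.5 CPM, since genes with few reads entered. With 1 CPM required in 3 libraries the stress and wound median was 115 CPM over fewer members. Leaving out 1 library at a time and filtering again, which kept 14130 to 14492 genes, gave a coefficient of variation from 23.8% to 33.0% and a detoxification median from 278 to 325 CPM. With the 13784 genes kept, the ranges were 23.3% to 33.0% and 303 to 325 CPM. Other scaling factors and thinning left the coefficient of variation between 28.2% and 28.5%. The glutathione and thioredoxin median lay between 696 and 729 CPM, but all its members passed the filter, so other filters were no check of it. Over 33 list medians and the 6 alternatives that kept all libraries, 179 values stayed within 1 SD and 19 moved further. Of the 19, 12 came without a filter on low counts, 6 with 1 CPM required in 3 libraries and 1 after thinning. Scaling factors balance out over the libraries, so other factors could hardly move a mean of 3 library medians and were no check of it. Without 1 of 3 libraries a mean over the same members cannot move by 1 SD of those libraries, apart from refitted scaling, so leaving out a library was no check of the stability of means. Krt4, for example, had a mean of 2075 CPM with C3 and 558 CPM without it. Depth limits genes near the floor of 0.124 to 0.165 CPM.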

Other observations

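The tests of depth, scaling and epithelial share and the tests on members with no shared bases were chosen after the result was seen. The other tests were set before their result was seen. Some genes had reads almost solely in library C4. Igkc, an immunoglobulin light chain gene, had 3 reads in C1, 5 in C3 and 672 in C4, and Ighg1, a heavy chain gene, had 0, 0 and 502 reads. Of the adipocyte list, 4 of 10 members had reads only in C4, with 570 reads of Cfd, 51 of Adipoq, 74 of Cidec and 53 of Retn. Other members were read in every library, such as Fabp4 with 63.2, 69.7 and 83.0 CPM and Lipe with 68.3, 56.8 and 74.6 CPM in C1, C3 and C4. Car3 of the same list depended more on C4, with a mean of 27.6 CPM that was 16.8 CPM without that library. Uox, urate oxidase, had 10 reads in C1, 0 in C3 and 654 in C4. Other genes had few or no reads in C3 but more in both C1 and C4, with 258, 1 and 1029 reads of Ptx3, a pentraxin gene, and 49, 0 and 452 of the cytokine gene Il19. These genes were chosen after their values were seen.

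The adipocyte list had a median of 46.2 ± 13.9 CPM (SD, n = 3) over 4 of 10 members, with a spread at the 98.5th percentile. Without a filter on low counts the median was 2.19 CPM. The nerve and glia list had 4.09 ± 1.98 CPM over 5 of 10 members, with 0.898 CPM without the filter and 13.8 CPM after thinning and filtering again, and its leading gene Tubb3, at 210 ± 32.4 CPM, is not confined to neurons. The erythrocyte list had 4.98 ± 0.900 CPM over 2 of 7 members. None of the 18 airway, thyroid and stomach genes passed the filter, and they held 0.000157% of all counts. The sex-linked list had a median of 47.0 ± 6.78 CPM over 4 of 8 members, and 19.9 CPM without the filter. The Y-linked gene Ddx3y had 70.2, 74.6 and 95.3 CPM in C1, C3 and C4, and Xist had 13, 1 and 0 reads.

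Library C4 stood above C3 in fibroblast genes, with a median log2 ratio of 2.18 (95% bootstrap interval over genes 1.86 to 2.34), and in stress and wound keratinocyte genes, with 1.20 (0.55 to 1.92). Depth acts on genes of the same level alike and scaling on all genes alike. Without factors beyond the total the fibroblast and stress ratios were 2.07 and 1.09, and after thinning 2.17 and 1.21. Random lists matched on mean CPM had median log2 ratios of 0.041 and 0.067, values that TMM scaling itself keeps small. The fibroblast and stress ratios exceeded those of the random lists by 2.14 (1.73 to 2.66) and 1.14 (0.386 to 1.94). A scaling factor would move these lists and the random lists alike, so the excess argues against depth and scaling. Lists and libraries were chosen after their difference was seen, so this excess is no test of the difference itself. The intervals cover genes and not the spread between libraries. A lower share of epithelial cells in C4 would raise all other cell types alike only if their mix stayed the same. The fibroblast ratio exceeded the endothelial ratio by 1.81 (1.42 to 2.36) and the skeletal muscle ratio by 2.27 (1.89 to 2.79). The ratios were 1.53 (0.90 to 1.75) for leukocyte, 0.51 for nerve and glia and -0.97 for smooth muscle genes. These values argue against a lower share with an unchanged mix of other cells. They cannot exclude a lower share with a changed mix, and C1 was not set against C4 here. A candidate explanation that stays open is that the tissue of C4 held more fibroblasts and leukocytes than that of C3, or these cells in another state. More of these cells would also mean a lower epithelial share. Beyond tissue makeup no biological explanation was tested, since the libraries share 1 labelled group.

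In lists of usually abundant genes, 11 members had a read density more than 10 times below the list's median, among them Gapdh at 10.1 CPM, Tagln at 1.76 CPM and Tnnc2 with 0 reads. Density was CPM over the deposited gene length, so a long gene can count as low without having few reads. Ttn at 157 CPM and Pfkp at 68.0 CPM may be low for that reason, and both stay in the counts below. An overlapping gene on the other strand may have taken reads of Tnnc2 (74.0% of its exon bases covered) and Tagln (67.9%), which make up 18.2% of the low members, against 1.51% of the 199 others (Fisher's exact test, two-sided p = 0.0230). The others with 50% or more covered were Fen1, Gins2 and Chaf1a. They had 0.702, 1.15 and 4.81 CPM per kilobase against a list median of 4.07. Fen1 and Gins2 thus also lay below their list median, and the contrast depends on the cutoff for a low member. Of the low members, 4 (Fdps, Slc16a3, Myh4 and Lmod1) had no exon base under a gene of the other strand, which argues against that source for them. Fdps had 26.7% of its exon bases under another gene on the same strand, and reads lost there were not tested. Near-identical copies cover more than the limit of 50% in 9.09% of the low members (Hspa1a), against 2.51% of the others (Fisher's exact test, two-sided p = 0.279), and 6 low members (Pfkp, Slc16a3, Tnnc2, Ttn, Lmod1 and Tagln) share no 50-base stretch with another annotated gene. For Gapdh and Fdps, reads lost to copies cannot be told apart from low expression, since 94.6% and 86.4% of the stretches of their most shared transcript of 500 bases or more occur in other genes, while Rpl10a, with 88.1%, had 833 CPM.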
